A study of Mus musculus with 36 samples.

How the data were processed

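The processed signals were used as deposited. Per the labels, each array holds total RNA from the left ventricle of 1 mouse. The values were treated as intensity on a linear scale, scaled per array by the submitters. Which program made them is not stated, and what "m5" in the labels means is not explained. The trimmed means (2% cut from each end) agreed to a ratio of 1.021, under the limit of 1.1 set in advance, so nothing was scaled again. Groups, contrasts, filters and the choice of genes to name were fixed before the data were examined.

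Control probe sets were left out. A floor of 19.2, the 25th percentile of all non-control values, was applied to the signals, which were then log2 transformed. A probe set was kept if it lay above the floor on 3 arrays or more, which left 9970. Of the 9977 measured probe sets 8724 map to 1 gene symbol in the annotation table, 346 to several and 907 to none, and 7417 genes are named. Gene positions are from GRCm38.p6.

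Differences were estimated with limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups over the 36 arrays (24 residual degrees of freedom), a moderated variance with a trend on mean signal (8.8 prior degrees of freedom), and Benjamini-Hochberg adjustment within each contrast. Standard errors are from this fit. Genes named as the largest rises or falls are the largest among probe sets with 1 symbol that passed, had no overlap between the arrays compared (for the average over times, the same sign at 5 or more times) and lay above the floor on each of these arrays. At 48 hours 443 of 586 met this, and on average over times 247 of 368. Genes fixed in advance and list members can lie beyond them in size. Replicate numbers recur across groups. Residuals of 32 pairs of arrays with the same number in different groups had correlations from -0.1 to 0.21, against -0.28 to 0.28 in 562 pairs with different numbers, so mice were treated as unpaired. 1 array has a title of 1 week and a description of 48 hours, and the title was used.

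The 30 gene lists were tested with camera at a preset correlation of 0.01, on 7415 genes, each by its probe set of highest mean signal. Of a panel of 34 genes fixed in advance, 28 were measured. Adjustment ran over all lists and contrasts in 2 families, 7 banding and 5 sham contrasts. A correlation estimated from the arrays and the fry test were run as alternatives. Of 210 list tests for banding 63 passed with the preset correlation, 21 with the estimated correlation and 42 with fry.

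The procedure was tried on changes added to simulated signals, 50 genes per size for banding at 48 hours. Of genes moved by 0.5, 1, 1.5 and 2 on the log2 scale it called 0%, 32%, 42% and 58%, and it also called 7 unchanged probe sets. Up to 1.5, more genes were missed than called, and at 2 many were still missed. A list of 54 genes moved by 0.5 was called (adjusted p = 1.46e-18), and none of 189 other list tests was, a single trial on independent genes that sets no error rate.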

Results

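Gene expression was measured in the left ventricle of 36 mice after aortic banding, a surgical narrowing of the aorta that makes the ventricle pump against a raised pressure, or after a sham operation. Mice were taken 1 hour, 4 hours, 24 hours, 48 hours, 1 week or 8 weeks after surgery, with 3 banded and 3 sham mice at each time and 1 array per mouse. Each array gave 12654 signals, of which 66 belonged to control probe sets. Of the 12588 other probe sets, 2611 (20.7%) were listed at 0 on every array, and 9970 entered the tests. The trimmed mean signal lay between 365.6 and 373.1 on the 36 arrays, and the highest signal was 49078. Pearson correlations across probe sets between arrays of 1 group ran from 0.829 to 0.945, and probe sets are not independent replicates.

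The arrays also carried the CreX control, which is no mouse gene. Its signal was 7051 to 12464 on the 6 arrays of 8 weeks and 12507 to 42037 on the other 30. Banded and sham mice (18 each, compared within times) differed by 0.08 in log2 CreX signal (two-sided permutation test, p = 0.59, adjusted p = 0.599). The log2 ratio of 3 prime to 5 prime signal, a measure of RNA integrity, differed by 0.05 for Gapdh (permutation p = 0.599, adjusted p = 0.599) and by -0.16 for Actb (permutation p = 0.0186, adjusted p = 0.0744). The log2 99th percentile of signal differed by -0.03 (permutation p = 0.486, adjusted p = 0.599). These 4 measures formed 1 family. At 48 hours the 99th percentile was 7914 to 9763 on banded and 9666 to 10901 on sham arrays.

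**Figure D1:**
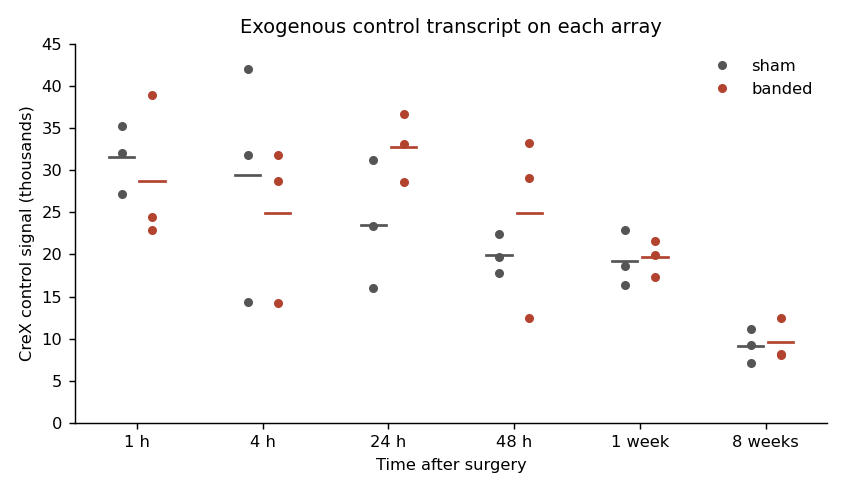
Signal of the CreX control transcript (vertical axis, in units of 1000) on each of the 36 arrays by time after surgery (horizontal axis), with sham mice in grey and banded mice in red. Points are arrays and dashes are group means of 3 arrays, and the 8 week arrays lie between 7051 and 12464.

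Banding against sham at each time asks which transcripts the pressure load moves, and when. The number of probe sets that passed an adjusted p of 0.05 was 17 at 1 hour, 3 at 4 hours, 107 at 24 hours, 586 at 48 hours, 53 at 1 week and 3 at 8 weeks. Each time had its own 6 mice. Of 210 list tests in the banding comparisons 63 passed, against a median of 22 and a highest count of 49 in groupings drawn at random. All changes below are log2 differences, banded minus sham, with their standard error from limma's fit over the 36 arrays, and signals are means with SD over 3 mice.

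**Figure D2:**
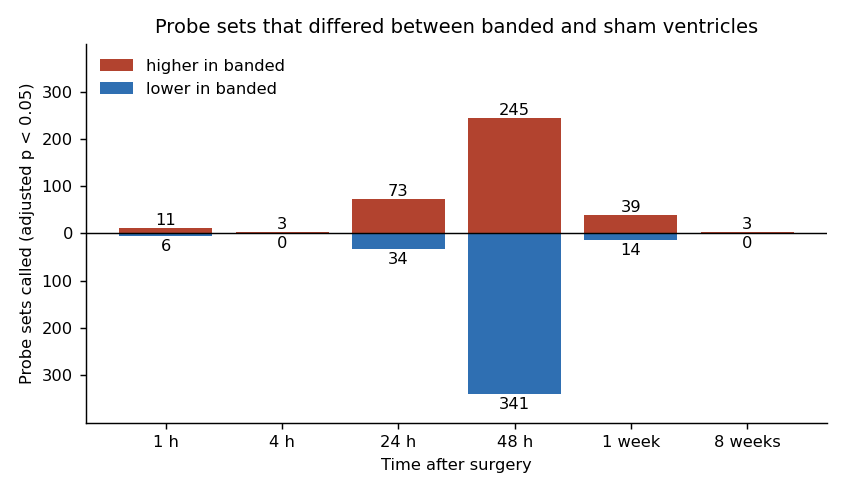
Number of probe sets that passed adjusted p = 0.05 (vertical axis) by time after surgery (horizontal axis), with those higher in banded ventricles drawn upward in red and those lower drawn downward in blue. The bars peak at 48 hours, with 245 higher and 341 lower.

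At 1 hour after surgery, banded ventricles had more Btg2, an antiproliferative gene (1.39 ± 0.27, adjusted p = 0.0167), and more Cdkn1a, an inhibitor of cyclin-dependent kinases (1.95 ± 0.41, adjusted p = 0.0308). Btg2 signal was 3430 ± 755 in banded and 1280 ± 24.6 in sham mice (SD, n = 3 each). Dgcr2 was 8.77-fold higher (3.13 ± 0.54, adjusted p = 0.00851), and Dynll2, a dynein light chain, was 2.53-fold higher (1.34 ± 0.23, adjusted p = 0.00851). Wipi2, an autophagy protein, Fxyd5, a regulator of the sodium pump, Nans, a sialic acid synthase, and the tropomyosin Tpm2 rose by 1.73 to 2.47. Sh3gl3, an endophilin, fell by 2.88 ± 0.57, the transcription factor Ebf2 fell by 2.60 ± 0.49, and the immunoglobulin segment Ighv5-12 fell by 1.48 ± 0.29. In all, 11 probe sets rose and 6 fell.

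Among the gene lists at 1 hour, smooth muscle and pericyte markers rose as a group with a median of 0.28 over 14 members (adjusted p = 0.00143, and adjusted p = 0.0392 with an estimated correlation). Of them Tpm2 rose on its own and 13 did not pass. The 27 immediate early genes had a median of 0.50 (adjusted p = 0.000147, but adjusted p = 0.126 with an estimated correlation), with Btg2 passing, 26 not passing, and 2 members higher when adjusted over the list alone. The 21 glucocorticoid-responsive genes had a median of 0.40 (adjusted p = 0.000719, but adjusted p = 0.147 with an estimated correlation), with Cdkn1a passing and 5 higher when adjusted over the list alone. The 44 inflammatory cytokines and acute phase genes had a median of 0.31 (adjusted p = 0.0196, but adjusted p = 0.359 with an estimated correlation), none passed, and adjusted over the list alone 3 were higher and 1 lower.

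The 1 hour count was 3 without banded mouse 16, 7 without sham mouse 6, 41 without sham mouse 5, 53 without sham mouse 7, 4 with array weights and 0 with only the 6 arrays of this time. It was 28 with a floor at the 40th percentile, where Wipi2 was at 1.65 (adjusted p = 0.0827). With that floor Dgcr2 was at 2.24, Sh3gl3 at -2.23 and Ebf2 at -1.90. A floor of 100 signal units, added after the data were seen, left Dgcr2 at 1.77 and Sh3gl3 at -1.77. It ended the calls of Wipi2 (1.33, adjusted p = 0.0803), Fxyd5 (1.62, adjusted p = 0.0607) and Ebf2 (-1.44, adjusted p = 0.0736). Array weights ended the calls of Cdkn1a, Btg2, Tpm2, Fxyd5, Sh3gl3, Nans, Wipi2 and Ighv5-12 (adjusted p from 0.0602 to 0.176). Without banded mouse 14 the inflammatory list was at 0.19 (adjusted p = 0.488) and the glucocorticoid list at 0.29 (adjusted p = 0.0899), and without sham mouse 7 Wipi2 was at 3.14. Of the 11 genes named by size Dgcr2 alone passed without each array in turn, and 9 lost the call without banded mouse 16. For 13 of the 17 probe sets, Dgcr2, Wipi2 and Dynll2 included, the 1 hour sham group lay farther from the mean of the other sham groups than the banded group did. Other probe sets of Wipi2 (-0.21, adjusted p = 0.949) and Cdkn1a (0.94, adjusted p = 0.326) did not pass.

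At 4 hours after surgery, Atf3, a stress-induced transcription factor, was 5.13-fold higher in banded ventricles (2.36 ± 0.42, adjusted p = 0.0314), at 3250 ± 3440 against 438 ± 78.2 (SD, n = 3 each). Xirp1, an actin-binding protein of the intercalated disc, rose by 1.48 ± 0.29 and Dnajb4, a heat shock co-chaperone, by 1.46 ± 0.28 (adjusted p = 0.0423 for each).

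The immediate early genes rose as a group at 4 hours with a median of 0.37 (adjusted p = 1.96e-07, and adjusted p = 0.0425 with an estimated correlation). Of the 27 members Atf3 passed, 26 did not, and 8 were higher when adjusted over the list alone. The 22 fetal and hypertrophy genes had a median of 0.37 (adjusted p = 5.73e-05, but adjusted p = 0.0921 with an estimated correlation), with Xirp1 passing and 7 higher when adjusted over the list alone. The inflammatory list had a median of 0.26 with no member passing and 1 higher when adjusted over the list alone (adjusted p = 0.000147, but adjusted p = 0.097 with an estimated correlation). Heat shock and unfolded protein response genes had a median of 0.24 (adjusted p = 0.0132, but adjusted p = 0.237 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.27 (adjusted p = 0.0119, but adjusted p = 0.316 with an estimated correlation). Neither list had a member passing. Adjusted over the list alone, 2 heat shock genes were higher and 1 lower, and 0 glucocorticoid-responsive genes passed.

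The 4 hour count of 3 moved by over 1.5 times when any of 29 of the 36 arrays was left out, from 0 without sham mouse 1, 2 or 3 to 30 without banded mouse 12. Atf3, Xirp1 and Dnajb4 each lost the call without banded mouse 10, without sham mouse 1, 2 or 3, or with only the 6 arrays of this time (adjusted p = 0.746 for each). Xirp1 (adjusted p = 0.116) and Dnajb4 (adjusted p = 0.258) also lost it without banded mouse 11. Atf3 was at 1.51 without banded mouse 10 and at 2.97 without banded mouse 12, and its other probe set, at 2.62, did not pass (adjusted p = 0.293). With 1 array of conflicting labels (banded mouse 1 of 1 week) put at 48 hours none of the 3 passed (adjusted p = 0.0732 for each), nor with a prior variance without trend, where Atf3 had adjusted p = 0.0828. Quantile normalization, array weights or a higher floor ended the calls of Xirp1 and Dnajb4, at adjusted p = 0.0559, 0.0655 and 0.0547. Heat shock genes were at 0.11 without banded mouse 10 (adjusted p = 0.404), and glucocorticoid-responsive genes at 0.29 without sham mouse 2 (adjusted p = 0.0512). Without the 3 arrays of low CreX signal (banded mouse 10 and sham mouse 3 of 4 hours, banded mouse 10 of 48 hours), left out after the data were seen, 0 passed, with Atf3 at 1.52, Xirp1 at 0.87 and Dnajb4 at 0.98, and the heat shock list was lost (adjusted p = 0.403).

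At 24 hours after surgery, genes of the stressed and hypertrophic heart muscle were higher in banded ventricles. Fhl1, a LIM-domain protein of striated muscle (chromosome X, 56731209 to 56793346 on GRCm38.p6), was 4.85-fold higher, at 15900 ± 6020 against 3110 ± 49.7 (SD, n = 3 each, 2.28 ± 0.32, adjusted p = 0.000138). Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985786 to 147987205), was 4.27-fold higher, at 26400 ± 8730 against 6010 ± 1260 (2.10 ± 0.36, adjusted p = 0.00204). The matrix genes Ccn2, a connective tissue growth factor, and Vcan, the proteoglycan versican, rose by 2.54 ± 0.42 and 2.93 ± 0.56, and Uck2, a uridine-cytidine kinase, by 2.40 ± 0.37. In all, 73 probe sets rose and 34 fell.

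Fetal and hypertrophy genes rose as a group at 24 hours with a median of 0.57 (adjusted p = 1.26e-09, and adjusted p = 0.0176 with an estimated correlation). Of its 22 members 6 rose, 16 did not pass and 9 were higher when adjusted over the list alone. Among them were skeletal actin, Acta1 (1.09 ± 0.22), and the LIM protein Csrp3 (0.98 ± 0.19). Ribosome biogenesis and nucleolus genes rose with a median of 0.40 (adjusted p = 0.000292, and adjusted p = 0.0295 with an estimated correlation). Nucleolin, Ncl, rose by 0.92 ± 0.18, 27 of 28 did not pass, and 2 were higher when adjusted over the list alone. The metallothioneins Mt2 (2.08 ± 0.38, adjusted p = 0.0052) and Mt1 (1.35 ± 0.31, adjusted p = 0.021) rose. Among genes above the floor on all 6 arrays and without overlap between the groups, the largest falls were in the ubiquitin ligase Wwp2 (-1.75 ± 0.44), the aldehyde oxidase Aox1 (-1.75 ± 0.44), Orc5 of the origin recognition complex (-1.62 ± 0.41), the calcium channel subunit Cacna1b (-1.53 ± 0.39) and Inca1 (-1.46 ± 0.33). Next came Ift81 of the intraflagellar transport (-1.38 ± 0.23), the forkhead factor Foxo3 (-1.36 ± 0.30) and Dynll2 (-1.20 ± 0.23). Dpysl3 (3.18 ± 0.66), the lipid phosphatase Mtm1 (2.95 ± 0.62) and the germ cell gene Dazl (2.32 ± 0.50) also rose, while a second probe set of Mtm1 was at -0.19 (adjusted p = 0.822). Quantile normalization ended the calls of Acta1 (0.70, adjusted p = 0.079) and Mt1 (1.12, adjusted p = 0.0537), and a floor at the 40th percentile those of Wwp2 (adjusted p = 0.0543) and Orc5 (adjusted p = 0.0589). With a floor of 100 units Wwp2 was at -1.22, Orc5 at -0.95, Dpysl3 at 2.10, Vcan at 2.33 and Dazl at 1.13. A prior variance without trend ended the calls of Aox1, Cacna1b, Foxo3, Serpina3n and Mt1 (adjusted p from 0.0544 to 0.0769). Aox1 lost its call with the conflicting array put at 48 hours (adjusted p = 0.0704), and Orc5 with array weights (adjusted p = 0.0716). Another Fhl1 probe set passed (2.75), unlike a dim one (-0.73).

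A further 7 lists passed at 24 hours with the preset correlation alone. The inflammatory list had a median of 0.35 (adjusted p = 2.6e-05, but adjusted p = 0.0857 with an estimated correlation). The acute phase gene Serpina3n (1.24 ± 0.27) and the oncostatin M receptor Osmr (1.15 ± 0.25) rose among its 44 members, and 4 were higher when adjusted over the list alone. Immediate early genes had a median of 0.45 with 3 of 27 rising (adjusted p = 0.000284, but adjusted p = 0.145 with an estimated correlation). Of these genes, adjusted over the list alone, 11 were higher and 1 lower. Matrix genes had a median of 0.20 with 4 of 54 rising (adjusted p = 0.001, but adjusted p = 0.242 with an estimated correlation), and adjusted over the list alone 14 were higher and 3 lower. Heat shock genes had a median of 0.28 with Hspa8, Hsp90aa1 and Hspa5 rising among 28 (adjusted p = 0.00157, but adjusted p = 0.113 with an estimated correlation). Of its members, 7 were higher and 1 lower when adjusted over the list alone. Macrophage and myeloid markers had a median of 0.38 (adjusted p = 0.00168, but adjusted p = 0.237 with an estimated correlation). Adult sarcomere genes had a median of 0.33 (adjusted p = 0.00983, but adjusted p = 0.555 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.24 (adjusted p = 0.0137, but adjusted p = 0.38 with an estimated correlation). None of the 3 lists had a member passing. With quantile normalization the sarcomere list was at 0.10 (adjusted p = 0.613) and the ribosomal list at 0.05 (adjusted p = 0.177), and with the CreX covariate they were at -0.11 (adjusted p = 0.654) and 0.05 (adjusted p = 0.096). Adjusted over the list alone, 0, 0 and 1 of their members were higher.

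Banded mouse 5 stood apart at 24 hours. Relative to the sham mean, its mean over extracellular matrix and its processing was 0.05 against 0.51 and 0.37 in banded mice 2 and 4. Its mean over fetal and hypertrophy genes was 0.50 against 0.67 and 0.67. The count of 107 was 280 without banded mouse 5, 61 without mouse 2, 11 without mouse 4, and 14, 179 and 59 without sham mice 11, 12 and 13. It was 2 with only the 6 arrays of this time, 61 with a prior variance without trend, 217 among probe sets above the median signal and 252 with the CreX signal as a covariate, a fit added after the data were seen. Of the 20 genes that passed among those named by size or fixed in advance, Ccn2, Uck2, Fhl1, Nppb and Ift81 passed without each array in turn. Without banded mouse 4, 14 of the 20 lost the call, with Aox1 at -0.96 and Foxo3 at -0.77. Without banded mouse 2 Cacna1b was at -0.81 (adjusted p = 0.336) and Mtm1 at 3.95, and without banded mouse 5 Ccn2 was at 3.16 and Uck2 at 3.09. Without banded mouse 2 the matrix list was at 0.02 (adjusted p = 0.0886), the macrophage list at 0.24 (adjusted p = 0.0773) and the cytosolic ribosomal list at 0.16 (adjusted p = 0.166). The ribosomal list was also lost without banded mouse 4 (0.15, adjusted p = 0.0549) or sham mouse 13 (0.15, adjusted p = 0.161). The sarcomere list was lost without banded mouse 5 (0.32, adjusted p = 0.214) or sham mouse 12 (0.15, adjusted p = 0.0667), and the heat shock list without sham mouse 11 (0.27, adjusted p = 0.132).

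At 48 hours after surgery, the ventricles showed a broad rise of matrix and myeloid genes and a fall of genes of energy metabolism. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874737), was 15.8-fold higher, at 6740 ± 3150 against 454 ± 256 (SD, n = 3 each, 3.98 ± 0.51, adjusted p = 3.05e-05). Postn, the matrix protein periostin (chromosome 3, 54359267 to 54391041), was 8.34-fold higher, at 4250 ± 1760 against 480 ± 79.9 (3.06 ± 0.41, adjusted p = 5.24e-05). Ccl2, a chemokine that attracts monocytes, was 24.1-fold higher, at 1380 ± 834 against 63.9 ± 51.4 (4.59 ± 0.92, adjusted p = 0.00247). In all, 245 probe sets rose and 341 fell.

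Matrix genes rose as a group with a median of 0.74 (adjusted p = 5.31e-14, and adjusted p = 0.0104 with an estimated correlation). Of 54 members 22 rose, 1 fell and 31 did not pass, and 28 were higher and 2 lower when adjusted over the list alone. Besides Timp1 and Postn they included tenascin C, Tnc (3.40 ± 0.65), the collagens Col1a1 (2.12 ± 0.37) and Col3a1 (1.98 ± 0.34), the proteoglycan Bgn (1.56 ± 0.24) and Fn1, fibronectin (1.14 ± 0.31). Macrophage and myeloid markers rose with a median of 0.94 (adjusted p = 6.19e-10, and adjusted p = 0.0215 with an estimated correlation). Of 31 members 10 rose, 21 did not pass and 17 were higher when adjusted over the list alone. Lgals3, galectin 3, rose by 3.63 ± 0.70, the Fc receptor Fcgr2b by 3.24 ± 0.65, cathepsin S, Ctss, by 1.94 ± 0.33, and lysozyme, Lyz2, by 1.72 ± 0.31. The stress genes Fhl1 (2.01 ± 0.32), Nppb (1.88 ± 0.36), Ccn2 (1.86 ± 0.42), Serpina3n (1.34 ± 0.27) and Acta1 (0.85 ± 0.22) were also higher. Tmem45a (2.92 ± 0.82), the hyaluronan receptor Cd44 (2.75 ± 0.77), the retinoic acid enzyme Aldh1a2 (2.73 ± 0.66) and the phagocyte oxidase subunit Ncf4 (2.73 ± 0.70) also rose. With quantile normalization Cd44 was at 2.37 (adjusted p = 0.0694). With a floor of 100 units Cd44 lost its call (0.98, adjusted p = 0.076). At that floor Ccl2 was at 3.55, Tnc at 2.78, Fcgr2b at 1.52, Tmem45a at 1.61, Aldh1a2 at 1.25 and Ncf4 at 1.28. With the conflicting array put at 48 hours Aldh1a2 (2.17, adjusted p = 0.061) and Ncf4 (2.18, adjusted p = 0.0795) lost their calls, and a prior variance without trend ended that of Fn1 (adjusted p = 0.0501). Another Fhl1 probe set passed (2.28), unlike a dim one (-0.83).

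Fatty acid oxidation genes fell as a group with a median of -0.77 (adjusted p = 1.42e-16, and adjusted p = 0.03 with an estimated correlation). Of 28 members 14 fell, 14 did not pass and 19 were lower when adjusted over the list alone. Genes of the mitochondrial respiratory chain and citrate cycle fell with a median of -0.54 (adjusted p = 1.16e-19, and adjusted p = 0.0425 with an estimated correlation). Of 74 members 24 fell and 50 did not pass, and adjusted over the list alone 44 were lower and 1 higher. Pdk4, a kinase that restrains pyruvate dehydrogenase, fell by 2.16 ± 0.52 (adjusted p = 0.0107). Among genes above the floor on all 6 arrays and without overlap, the largest falls outside these lists were in Crebbp, a histone acetyltransferase (-2.77 ± 0.47), Rnf2, a polycomb ubiquitin ligase (-2.76 ± 0.47), Gpcpd1 (-2.65 ± 0.64) and Xdh, xanthine dehydrogenase (-2.43 ± 0.46). They were followed by Inmt (-2.37 ± 0.57), Gstt1 (-2.29 ± 0.61), Aldh9a1 (-2.02 ± 0.50) and Ephx1, an epoxide hydrolase (-2 ± 0.55). Other probe sets of Rnf2 (0.18 and 0.69), Gpcpd1 (0.59) and Cd44 (0.00 and 0.45) did not pass. Gstt1 (-1.95, adjusted p = 0.0594) and Ephx1 (-1.61, adjusted p = 0.102) lost their calls with the conflicting array put at 48 hours, where Crebbp was at -2.17 and Rnf2 at -2.05. With a floor of 100 units Rnf2 was at -1.65, Inmt at -1.77, Gstt1 at -1.65 and Aldh9a1 at -1.27.

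A further 8 lists passed at 48 hours with the preset correlation alone. Fetal and hypertrophy genes had a median of 0.59 with 5 of 22 rising, the same 5 when adjusted over the list alone (adjusted p = 4.96e-05, but adjusted p = 0.0913 with an estimated correlation). Cell cycle genes had a median of 0.77 (adjusted p = 8.52e-05, but adjusted p = 0.0913 with an estimated correlation). Kif11 (2.99 ± 0.67), Cdk1 (1.90 ± 0.57) and Ccnb2 (1.13 ± 0.35) rose among its 45 members, and 8 were higher when adjusted over the list alone. The inflammatory list had a median of 0.73 with 6 of 44 rising, and 10 higher and 1 lower when adjusted over the list alone (adjusted p = 0.000547, but adjusted p = 0.142 with an estimated correlation). Endothelial markers had a median of -0.42 (adjusted p = 0.00308, but adjusted p = 0.0801 with an estimated correlation). Vwf (-1 ± 0.21) and Emcn (-0.61 ± 0.17) fell among 21, and 5 were lower and 1 higher when adjusted over the list alone. Calcium handling and ion channel genes had a median of -0.33 (adjusted p = 0.00478, but adjusted p = 0.093 with an estimated correlation). Abcc9, Hrc and the ryanodine receptor Ryr2 fell among 30, and 3 were lower when adjusted over the list alone. Neutrophil markers had a median of 0.73 with Ncf4 and Ncf1 rising among 17, and 2 higher when adjusted over the list alone (adjusted p = 0.023, but adjusted p = 0.256 with an estimated correlation). Glucocorticoid-responsive genes had a median of -0.35 with 4 of 21 falling, and 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0349, but adjusted p = 0.416 with an estimated correlation). Glycolysis genes had a median of -0.23 with 4 of 17 falling, and 5 lower when adjusted over the list alone (adjusted p = 0.0413, but adjusted p = 0.356 with an estimated correlation). Quantile normalization ended the calls of the neutrophil (0.56, adjusted p = 0.0636), glucocorticoid (-0.39, adjusted p = 0.131) and glycolysis lists (-0.14, adjusted p = 0.61). Among probe sets above the median signal the calcium handling, glycolysis and glucocorticoid lists did not pass (adjusted p = 0.0799, 0.0544 and 0.241). Glycolysis genes were also lost with array weights (adjusted p = 0.0679) and with the conflicting array put at 48 hours (adjusted p = 0.0976), and the glucocorticoid list with a floor of 100 units (adjusted p = 0.0509).

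Banded mouse 10 of 48 hours had a CreX signal of 12507 and a mean over macrophage and myeloid markers of 0.42 against 1.30 and 1.23 in banded mice 7 and 8. The count of 586 was 1002 without it, 321 without mouse 7, 106 without mouse 8, and 237, 386 and 257 without sham mice 15, 16 and 17. It was 1077 with array weights, 384 with a prior variance without trend, 375 when 1 array with conflicting labels was put at 48 hours, and 0 with only the 6 arrays of this time. Of the 26 genes that passed among those named by size or fixed in advance, 14, Timp1, Postn, Ccl2, Crebbp and Xdh among them, passed without each array in turn. Without banded mouse 8 the 12 others lost the call, with Inmt at -1.72 and Gstt1 at -1.69, and Xdh, which kept it, was at -1.84. Without banded mouse 10 Tnc was at 4.11, Aldh1a2 at 3.61, Gpcpd1 at -3.52, Gstt1 at -2.89, Aldh9a1 at -2.83 and Pdk4 at -2.96. Without banded mouse 7 Aldh1a2 at 2.12 (adjusted p = 0.0886) and Aldh9a1 at -1.18 (adjusted p = 0.156) did not pass. Without sham mouse 16 Timp1 was at 3.37 and Ccl2 at 3.89, without sham mouse 17 Tnc was at 2.79 and Ccl2 at 5.19, and without sham mouse 15 Tmem45a was at 3.69. The neutrophil list was lost without banded mouse 7 (adjusted p = 0.103). The glycolysis list was lost without banded mouse 8 and sham mice 15 and 16 (-0.03, -0.15 and -0.24, adjusted p = 0.225, 0.0579 and 0.0509). The glucocorticoid list was lost without banded mice 7 and 8 and sham mice 15 and 17 (adjusted p = 0.0619, 0.0651, 0.0862 and 0.0751).

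**Figure D3:**
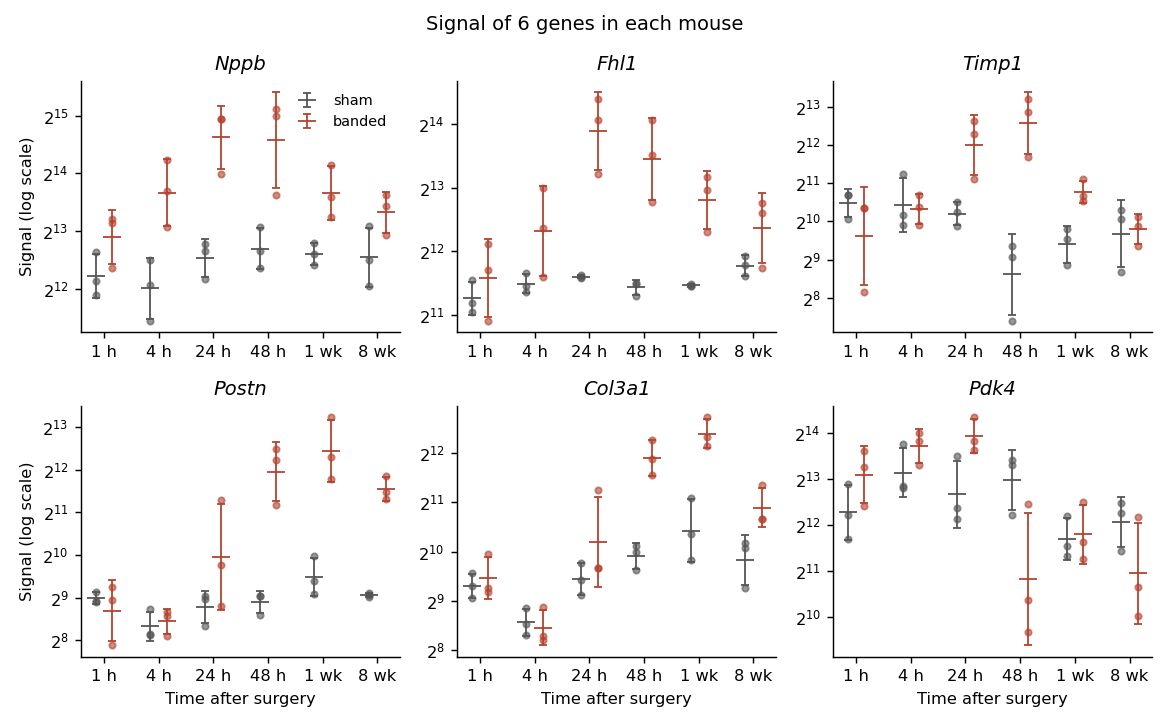
Signal (vertical axes, log scale) of Nppb, Fhl1, Timp1, Postn, Col3a1 and Pdk4 in each mouse by time after surgery (horizontal axes), with sham mice in grey and banded mice in red. Points are mice, dashes are means of the log2 signal and bars are 1 SD on the log2 scale (n = 3), and Postn in banded mice lies above sham at 48 hours, 1 week and 8 weeks by 3.06, 2.95 and 2.48.

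At 1 week after surgery, genes of the collagen matrix and of the fetal heart programme were higher in banded ventricles. Postn was 7.74-fold higher, at 6050 ± 3170 against 740 ± 241 (SD, n = 3 each, 2.95 ± 0.41, adjusted p = 0.000331). Col3a1 was 3.91-fold higher, at 5460 ± 1180 against 1470 ± 642 (1.97 ± 0.34, adjusted p = 0.00305). Nppa, which encodes atrial natriuretic peptide, was 3.68-fold higher (1.88 ± 0.43, adjusted p = 0.0354), and Myh7, the beta myosin heavy chain, 2.47-fold higher, at 18000 ± 2220 against 7280 ± 596 (1.30 ± 0.27, adjusted p = 0.0128). In all, 39 probe sets rose and 14 fell.

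Matrix genes rose as a group at 1 week with a median of 0.90 (adjusted p = 3.46e-31, and adjusted p = 0.000245 with an estimated correlation). Of 54 members 20 rose, 34 did not pass and 26 were higher when adjusted over the list alone. They included Col5a2 (2.76 ± 0.46), Col1a1 (1.92 ± 0.37), Col1a2 (1.88 ± 0.32) and Bgn (1.48 ± 0.24), and Ltbp2 (1.98 ± 0.48), Mfap5 (1.92 ± 0.36) and Ccn2 (1.82 ± 0.42) also rose. Fibroblast markers rose with a median of 0.27 (adjusted p = 3.53e-05, and adjusted p = 0.0231 with an estimated correlation). Among the 20 members 5 rose, and 7 were higher and 1 lower when adjusted over the list alone. Fetal and hypertrophy genes rose with a median of 0.61 (adjusted p = 8.73e-09, and adjusted p = 0.0215 with an estimated correlation). Myh7, Nppa, Acta1 (0.92 ± 0.22) and Fhl1 (1.34 ± 0.32) rose among 22, and 9 were higher when adjusted over the list alone. Macrophage and myeloid markers rose as a group with a median of 0.62 (adjusted p = 3.15e-09, and adjusted p = 0.0268 with an estimated correlation). No single member passed, and 3 were higher when adjusted over the list alone.

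Genes of the mitochondrial respiratory chain and citrate cycle fell as a group at 1 week with a median of -0.35 (adjusted p = 9.17e-19, and adjusted p = 0.0468 with an estimated correlation). None of the 74 members passed, and 12 were lower when adjusted over the list alone. Fatty acid oxidation genes had a median of -0.47 (adjusted p = 2.07e-10, but adjusted p = 0.093 with an estimated correlation). Ech1 (-0.80 ± 0.18), Eci1 (-0.81 ± 0.19) and Etfb (-0.74 ± 0.17) fell among 28, and 10 were lower and 1 higher when adjusted over the list alone. Of genes above the floor on all 6 arrays and without overlap, those that fell most were Gamt, an enzyme of creatine synthesis (-1.73 ± 0.42), Isoc1 (-1.61 ± 0.34), the peroxisomal protein Pex11a (-1.28 ± 0.30), Cmbl (-1.21 ± 0.23), the ephrin Efnb3 (-1.09 ± 0.23), the co-chaperone Fkbp4 (-0.99 ± 0.23) and the homeodomain protein Hopx (-0.89 ± 0.21). Quantile normalization ended the calls of Fkbp4, Hopx and Eci1 (adjusted p = 0.0508 for each) and of Ltbp2 (adjusted p = 0.0522). Other probe sets of Col3a1 (1.20), Mfap5 (0.14), Efnb3 (-0.50), Fkbp4 (-0.57) and Fhl1 (1.33, adjusted p = 0.115, and 1.01, adjusted p = 0.873) did not pass.

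Another 7 lists passed at 1 week with the preset correlation alone. Cell cycle genes had a median of 0.55 with no member passing (adjusted p = 0.000147, but adjusted p = 0.093 with an estimated correlation). Interferon response genes had a median of 0.43, and Ifit1 rose by 2.99 ± 0.59 (adjusted p = 0.000159, but adjusted p = 0.0939 with an estimated correlation). Atrial markers had a median of 0.52 with Nppa and Clu rising among 12 (adjusted p = 0.0168, but adjusted p = 0.145 with an estimated correlation). Smooth muscle and pericyte markers had a median of 0.25, with Tagln rising by 0.94 ± 0.19 (adjusted p = 0.0392, but adjusted p = 0.157 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.31 (adjusted p = 0.0355, but adjusted p = 0.416 with an estimated correlation). Calcium handling genes had a median of -0.14 (adjusted p = 0.0375, but adjusted p = 0.237 with an estimated correlation). The inflammatory list had a median of 0.15 (adjusted p = 0.0414, but adjusted p = 0.438 with an estimated correlation). No member of these 3 lists passed. With quantile normalization calcium handling genes were at -0.12 (adjusted p = 0.0998). With the conflicting array put at 48 hours cell cycle genes were at 0.27 (adjusted p = 0.146), smooth muscle markers at 0.27 (adjusted p = 0.0609), the inflammatory list at 0.26 (adjusted p = 0.07) and calcium handling genes at -0.10 (adjusted p = 0.084). The inflammatory list (adjusted p = 0.113) and smooth muscle markers (adjusted p = 0.0868) did not pass among probe sets above the median signal. Adjusted over the list alone, 0 cell cycle, 2 interferon, 3 atrial, 1 smooth muscle, 2 glucocorticoid-responsive and 1 inflammatory genes were higher, and 2 calcium handling genes were lower.

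Banded mouse 1 of 1 week is the array of conflicting labels. The count of 53 was 20 both without this array and with it put at 48 hours. The count was 4 without banded mouse 5, 21, 14 and 24 without sham mice 5, 6 and 7, 20 with a prior variance without trend and 8 with only the 6 arrays of this time. Of the 20 genes that passed among those named by size or fixed in advance Postn alone passed without each array in turn. Without banded mouse 5, 19 of these 20 lost the call, with Ccn2 at 1.16. With the conflicting array put at 48 hours the calls of Nppa, Acta1, Fhl1, Ccn2, Ltbp2, Gamt, Isoc1, Pex11a, Cmbl, Hopx and Eci1 were lost (adjusted p from 0.0579 to 0.391). A prior variance without trend ended the calls of Nppa, Acta1, Ccn2, Fkbp4, Hopx, Eci1, Fhl1, Myh7, Ltbp2, Gamt, Isoc1, Pex11a and Efnb3 (adjusted p from 0.0666 to 0.131). Without the arrays of low CreX signal Ltbp2 was lost (adjusted p = 0.0705).

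Single arrays also ended list calls at 1 week. The inflammatory list did not pass without banded mice 1 and 3 and sham mice 5 and 6 (adjusted p = 0.0649, 0.19, 0.0598 and 0.168), and was at 0.04 without banded mouse 3. Calcium handling genes did not pass without the same 4 mice (adjusted p = 0.0904, 0.0738, 0.144 and 0.0923). Smooth muscle markers were lost without banded mice 1 and 3, sham mice 6 and 7 and sham mouse 5 of 8 weeks (adjusted p = 0.0586, 0.0863, 0.0868, 0.0866 and 0.0531). Cell cycle genes were lost without banded mouse 1 (adjusted p = 0.144) and atrial markers without banded mouse 5 and sham mouse 7 (adjusted p = 0.077 and 0.0511). Glucocorticoid-responsive genes were at 0.16 without banded mouse 5 and 0.30 without sham mouse 6 (adjusted p = 0.974 and 0.219).

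At 8 weeks after surgery, 3 matrix or secreted genes were higher in banded ventricles and no probe set was lower. Postn was 5.57-fold higher, at 3020 ± 595 against 535 ± 17.5 (SD, n = 3 each, 2.48 ± 0.41, adjusted p = 0.00767). Bgn was 2.63-fold higher, at 9410 ± 3260 against 3470 ± 760 (1.39 ± 0.24, adjusted p = 0.00767). Serpinf1, pigment epithelium-derived factor, was 2.48-fold higher, at 1010 ± 289 against 398 ± 60.7 (1.31 ± 0.23, adjusted p = 0.0091).

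Matrix genes rose as a group at 8 weeks with a median of 0.50 (adjusted p = 1.34e-24, and adjusted p = 0.000533 with an estimated correlation). Postn and Bgn rose, 52 of 54 did not pass and 15 were higher when adjusted over the list alone. Fibroblast markers rose with a median of 0.49 (adjusted p = 2.29e-08, and adjusted p = 0.00359 with an estimated correlation). No member passed and 6 of 20 were higher when adjusted over the list alone, with Col1a1 at 1.51 ± 0.37 (adjusted p = 0.241). Fatty acid oxidation genes had a median of -0.35 (adjusted p = 8.93e-12, but adjusted p = 0.0837 with an estimated correlation). Fetal and hypertrophy genes had a median of 0.18 (adjusted p = 0.000116, but adjusted p = 0.093 with an estimated correlation). Neither list had a member passing, and adjusted over the list alone 3 of the former were lower and 2 of the latter higher. Mitochondrial genes had a median of -0.08 (adjusted p = 0.018, but adjusted p = 0.698 with an estimated correlation). Calcium handling genes also had a median of -0.08 (adjusted p = 0.0229, but adjusted p = 0.176 with an estimated correlation). Macrophage markers had a median of 0.23 (adjusted p = 0.0278, but adjusted p = 0.438 with an estimated correlation). Macrophage markers were at 0.17 with a floor at the 40th percentile (adjusted p = 0.114) and 0.11 with a floor of 100 units (adjusted p = 0.229). Among probe sets above the median signal they (adjusted p = 0.14) and calcium handling genes (adjusted p = 0.0526) did not pass. In these 3 lists 0 members passed, and 0 when adjusted over the list alone.

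The 8 week count of 3 was 0 without banded mouse 2, banded mouse 4 or sham mouse 5, 12 without banded mouse 1, 5 without sham mouse 6 and 5 without banded mouse 5 of 24 hours. It was 31 with array weights and 1 with only the 6 arrays of this time. Postn and Bgn lost their calls without each of banded mice 2 and 4 and sham mouse 5, and Serpinf1 without these or sham mouse 7 and with quantile normalization (1.20, adjusted p = 0.0683). Serpinf1 also lost it with the conflicting array put at 48 hours (adjusted p = 0.104), and Bgn with a prior variance without trend (adjusted p = 0.0569). The mitochondrial list was lost without banded mice 1 and 2 and sham mice 6 and 7 (adjusted p = 0.71, 0.267, 0.179 and 0.337), with medians from -0.08 to -0.02. Calcium handling genes were lost without the same 4 mice (adjusted p = 0.0678, 0.281, 0.181 and 0.163), with medians from -0.16 to -0.02. Macrophage markers were lost without banded mouse 2 and sham mice 5 and 7 (adjusted p = 0.13, 0.0809 and 0.122).

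**Figure D4:**
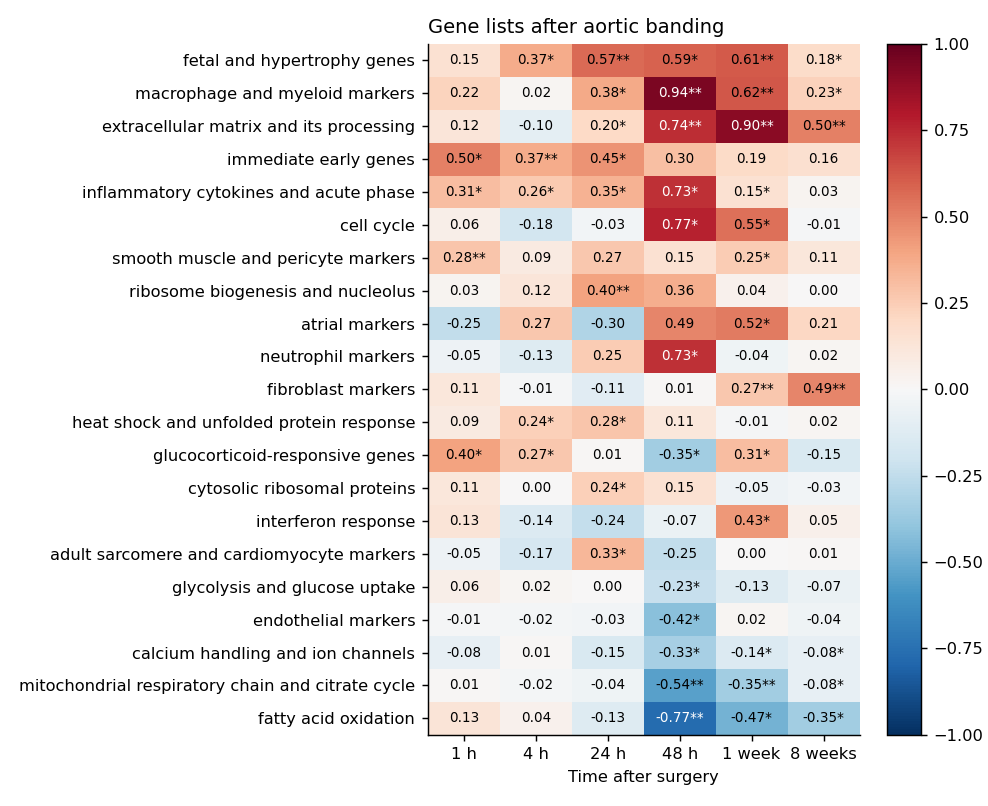
Median log2 difference, banded minus sham, of the gene lists that passed at 1 time or more (vertical axis) by time after surgery (horizontal axis), in red for higher and blue for lower. A single star marks adjusted p under 0.05 with the preset correlation and a double star a list that also passed with an estimated correlation, as matrix genes did at 48 hours, 1 week and 8 weeks with medians of 0.74, 0.90 and 0.50.

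Averaged over the 6 times, 18 banded against 18 sham mice, 218 probe sets were higher and 150 lower. Nppb was 2.56-fold higher (1.36 ± 0.15, adjusted p = 2.13e-07) and Fhl1 2.34-fold higher (1.23 ± 0.13, adjusted p = 2.13e-07), both with a positive difference at each of the 6 times. Postn (1.58 ± 0.17), Ccn2 (1.55 ± 0.17), Uck2 (1.40 ± 0.15), Col5a2 (1.36 ± 0.19), Mt2 (1.30 ± 0.16), Vcan (1.27 ± 0.23) and the protease Prss23 (1.25 ± 0.22) were the other largest rises among genes above the floor on every array and of the same sign at 5 or more times. Of the genes fixed in advance, Ccl2 (2.33 ± 0.38), Atf3 (1.1 ± 0.17), Nppa (1.01 ± 0.18), Serpina3n (1 ± 0.11), Acta1 (0.65 ± 0.09) and Myh7 (0.62 ± 0.11) rose. Among the same kind of genes, the largest falls were in Inmt (-1.11 ± 0.23), the growth factor Egf (-1 ± 0.26), Gpn3 (-0.91 ± 0.23) and the laminin Lamb3 (-0.85 ± 0.18). Ift81 (-0.71 ± 0.09), Gdap10 (-0.67 ± 0.13), Efnb3 (-0.65 ± 0.09) and Mlf1 (-0.65 ± 0.16) followed.

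Of the lists, 6 rose on average over the times and passed with both correlations. Matrix genes had a median of 0.46 with 28 of 54 rising (adjusted p = 1.45e-25, and adjusted p = 0.000533 with an estimated correlation). Fetal and hypertrophy genes had a median of 0.34 with 9 of 22 rising (adjusted p = 2.87e-15, and adjusted p = 0.00213 with an estimated correlation). Macrophage and myeloid markers had a median of 0.38 with 8 of 31 rising (adjusted p = 3.92e-12, and adjusted p = 0.0116 with an estimated correlation). The inflammatory list had a median of 0.26 with 8 of 44 rising (adjusted p = 1.99e-09, and adjusted p = 0.0187 with an estimated correlation). Immediate early genes had a median of 0.40 with 9 of 27 rising (adjusted p = 2.29e-08, and adjusted p = 0.03 with an estimated correlation). Smooth muscle and pericyte markers had a median of 0.16 with 3 of 14 rising and 1 falling (adjusted p = 0.000711, and adjusted p = 0.03 with an estimated correlation). Adjusted over the list alone, 31, 15, 15, 17, 12 and 6 of their members were higher, and 1 matrix, 1 immediate early and 1 smooth muscle gene was lower.

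Other lists passed on average over the times with the preset correlation alone. Fatty acid oxidation genes had a median of -0.24 with 10 of 28 falling, Eci1 (-0.47) and Hadh (-0.40) among them (adjusted p = 2.04e-10, but adjusted p = 0.093 with an estimated correlation). Mitochondrial genes had a median of -0.17 with 10 of 74 falling (adjusted p = 1.22e-13, but adjusted p = 0.093 with an estimated correlation). Of the members of these 2 lists, 16 and 24 were lower when adjusted over the list alone. Fibroblast markers had a median of 0.11 (adjusted p = 0.0027, but adjusted p = 0.0913 with an estimated correlation), and adjusted over the list alone 6 were higher and 3 lower. Calcium handling genes had a median of -0.12 (adjusted p = 0.00653, but adjusted p = 0.097 with an estimated correlation), with 4 lower when adjusted over the list alone. Cell cycle genes had a median of 0.20 (adjusted p = 0.00769, but adjusted p = 0.255 with an estimated correlation), with 1 higher when adjusted over the list alone. Ribosome biogenesis genes had a median of 0.14 (adjusted p = 0.00991, but adjusted p = 0.093 with an estimated correlation), and adjusted over the list alone 6 were higher and 1 lower. Heat shock genes had a median of 0.07 (adjusted p = 0.0229, but adjusted p = 0.284 with an estimated correlation), with 7 higher when adjusted over the list alone. Calcium handling genes did not pass among probe sets above the median signal (adjusted p = 0.0651), nor heat shock genes without the arrays of low CreX signal (adjusted p = 0.118). Heat shock genes were also lost without banded mouse 14 of 1 hour (adjusted p = 0.0525), banded mouse 10 of 48 hours (adjusted p = 0.0644) or sham mouse 11 of 24 hours (adjusted p = 0.0955). With a floor of 100 units Prss23 was at 0.50, and without the arrays of low CreX signal Egf had adjusted p = 0.0526. Other probe sets of Efnb3 (-0.23) and Fhl1 (-0.09) did not pass, but a brighter one of Fhl1 did (1.47). Of the genes named here, 29 of the 31 that passed did so without each array in turn, the exceptions being Tnc (0.91 ± 0.27, adjusted p = 0.0474) and Fn1 (0.44 ± 0.13, adjusted p = 0.0388). A prior variance without trend also ended these 2 calls (adjusted p = 0.0657 and 0.0811). Tnc was also lost with the conflicting array put at 48 hours (adjusted p = 0.124) and the CreX covariate (adjusted p = 0.0502), and Fn1 with quantile normalization (adjusted p = 0.0506).

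A moderated F test asked whether the banding difference depended on time, and 114 probe sets passed. Dynll2 had the smallest p (F = 18.5, adjusted p = 0.000102), with differences of 1.34, -0.99, -1.20, -1.08, 0.08 and 0.13 from 1 hour to 8 weeks. Postn (F = 12.7, adjusted p = 0.00135) went from -0.30, 0.11 and 1.17 to 3.06, 2.95 and 2.48, and Timp1 (F = 11.6, adjusted p = 0.00261) from -0.87, -0.11 and 1.81 to 3.98, 1.37 and 0.11. Bgn (F = 11.2) was at 1.56, 1.48 and 1.39 from 48 hours on, and the GTPase Rraga (F = 11.2) at 1.08 at 1 hour and -1.39 at 48 hours. Mtm1 (F = 10.3) and Pcyox1 (F = 9.69) also passed.

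The count of 114 was 11 with the conflicting array put at 48 hours, where Rraga, Mtm1 and Pcyox1 did not pass (adjusted p = 0.0857, 0.081 and 0.0924), 26 with a prior variance without trend, 237 with array weights and 295 without the 3 arrays of low CreX signal. It moved by over 1.5 times without any of 15 arrays, being 30, 67 and 367 without banded mice 8, 7 and 10 of 48 hours and 34, 72 and 36 without sham mice 15, 16 and 17 of 48 hours. It was 49, 75 and 63 without banded mice 14, 15 and 16 of 1 hour and 59 without sham mouse 6 of 1 hour. For the other arrays it was 61 and 65 without banded mice 10 and 11 of 4 hours, 68 and 74 without sham mice 2 and 3 of 4 hours, and 69 without sham mouse 6 of 1 week.

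Sham-operated ventricles were compared over time to describe what follows the operation itself, with the 8 week sham mice, the farthest from surgery, as the reference. The 5 comparisons share those 3 mice and are not independent, and the labels give no batch or scan date, so time and batch cannot be told apart. The 8 week sham arrays differed from the 15 other sham arrays by -1.39 in log2 CreX signal (two-sided exact permutation test, p = 0.00123, adjusted p = 0.00246). They differed by -0.37 in the log2 99th percentile of signal (exact p = 0.00123, adjusted p = 0.00246). They differed in the log2 3 prime to 5 prime ratio by 0.38 for Gapdh (exact p = 0.0098, adjusted p = 0.0131) and 0.32 for Actb (exact p = 0.0159, adjusted p = 0.0159). Over all 6 sham groups 579 probe sets passed the F test, with Pik3r1, a regulatory subunit of phosphoinositide kinase, at the smallest p (F = 42.6, adjusted p = 2.04e-09). The receptor Nrp1 (F = 24.2), Gdap10 (F = 19.3), Mtm1 (F = 17) and the nuclear receptor Ppara (F = 15.7) followed.

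Contractile genes gave a brighter signal on the earlier sham arrays than at 8 weeks. Myh6, the alpha myosin heavy chain, was higher by 1.56, 1.42, 1.35, 1.32 and 1.22 at 1 hour, 4 hours, 24 hours, 48 hours and 1 week, each with an SE of 0.29 and passing in the fit to all arrays. Myh6 lost its call at all 5 times with quantile normalization (0.57, 0.53, 0.61, 0.67 and 0.61) and with the CreX covariate (0.41, 0.42, 0.50, 0.59 and 0.53). Without sham mouse 5 of 8 weeks it was at 0.98, 0.90, 0.87 and 0.78 from 4 hours to 1 week and did not pass (adjusted p = 0.0698, 0.204, 0.289 and 0.527). Its call was also lost at 24 hours without sham mice 11 and 13 (adjusted p = 0.0917 and 0.0539), at 48 hours without sham mice 15 and 17 (adjusted p = 0.07 and 0.0706) and at 1 week without sham mouse 5, 6 or 7 (adjusted p = 0.0606, 0.12 and 0.202). At 1 week a prior variance without trend, the replicate block and the unpaired fit of the same arrays ended it too (adjusted p = 0.0798, 0.0921 and 0.172). At 1 hour the myosin light chain Myl2 was higher by 4.63 ± 1.25 and the ribosomal gene Rpl41 by 3.58 ± 0.76, which was 0.67 with the CreX covariate (adjusted p = 0.819). Without sham mouse 5 of 8 weeks Myl2 at 3.85 (adjusted p = 0.142) and Rpl41 at 2.53 (adjusted p = 0.0674) did not pass, and without sham mouse 7 of 8 weeks they were at 5.42 and 4.23. Myl2 did not pass without sham mouse 6 of 8 weeks (adjusted p = 0.0726), without sham mouse 6 or 7 of 1 hour (adjusted p = 0.0698 and 0.0534) or with a prior variance without trend (adjusted p = 0.0519). Of the 17 adult sarcomere genes 13, 12, 5, 2 and 1 were called higher at the 5 times, with medians of 1.25, 1.16, 0.80, 0.66 and 0.65 (adjusted p = 5.54e-13, 1.12e-15, 2.75e-12, 3.43e-16 and 1.3e-11, but adjusted p = 0.0616, 0.0463, 0.0663, 0.0463 and 0.073 with an estimated correlation). Of these, 14, 13, 12, 14 and 10 were higher when adjusted over the list alone. Mitochondrial genes had medians of 0.40, 0.47, 0.30, 0.39 and 0.38 (adjusted p = 2.44e-08, 2.94e-14, 3.46e-08, 3.29e-19 and 2.12e-19, but adjusted p = 0.31, 0.0979, 0.313, 0.0616 and 0.0616 with an estimated correlation). Of 74 members 22, 20, 11, 11 and 8 were called higher, and 33, 32, 28, 28 and 28 higher when adjusted over the list alone. Quantile normalization left medians of 0.10, 0.09, 0.02, 0.03 and 0.04 and ended the mitochondrial call at 1 hour (adjusted p = 0.0635), 24 hours (adjusted p = 0.392), 48 hours (adjusted p = 0.475) and 1 week (adjusted p = 0.0641).

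Interferon response genes were lower on the earlier sham arrays than at 8 weeks, with medians of -0.98, -0.93, -0.50, -0.62 and -0.37 and 8, 8, 2, 3 and 1 of 31 called lower (adjusted p = 2.9e-07, 4.15e-11, 0.000307, 1.12e-07 and 5.21e-05, and adjusted p = 0.049, 0.0377, 0.146, 0.0463 and 0.09 with an estimated correlation). Adjusted over the list alone 11, 11, 6, 8 and 7 were lower, and 1 was higher at 1 hour. The guanylate-binding protein Gbp2 was at -2.63 ± 0.54 at 4 hours, and the GTPase Irgm2 at -2.18, -2.49 and -2.27 (SE 0.36 each) at 24 hours, 48 hours and 1 week. Class II antigen presentation genes had medians of -0.53, -0.55, -0.57, -0.92 and -0.92 (adjusted p = 0.0166, 0.000769, 0.00428, 1.31e-05 and 8.64e-05, and adjusted p = 0.168, 0.0616, 0.09, 0.0463 and 0.0463 with an estimated correlation). Of 11 members 3, 4, 3, 3 and 4 were lower when adjusted over the list alone, with H2-Aa at -1.90 ± 0.37 at 24 hours. With the CreX covariate Gbp2 was at -1.83 (adjusted p = 0.298) and H2-Aa at -1.83 (adjusted p = 0.0878), and with array weights the class II list at 24 hours was at -0.25 (adjusted p = 0.104). The class II list was lost at 1 hour without sham mouse 5 (adjusted p = 0.0687) or 6 of 8 weeks (-0.15, adjusted p = 0.0541), and at 24 hours without sham mouse 12 (-0.19, adjusted p = 0.075). Without sham mouse 6 of 8 weeks the interferon list was at 0.00 at 24 hours and -0.23 at 1 week (adjusted p = 0.0861 for each), and Irgm2 at -1.59 and -1.68. Gbp2 did not pass without sham mouse 1 of 4 hours (-1.83, adjusted p = 0.0604) or sham mouse 6 of 8 weeks (adjusted p = 0.0517), and was at -3.24 without sham mouse 3 of 4 hours. H2-Aa did not pass without sham mouse 11 of 24 hours or sham mice 5 and 6 of 8 weeks (adjusted p = 0.0917, 0.0615 and 0.0612). With the replicate block Irgm2, Mef2c and Atp7a did not pass at 1 week (adjusted p = 0.0661 for each), nor did Irgm2 in the unpaired fit of the same arrays (adjusted p = 0.0625). Glucocorticoid-responsive genes were higher at 4 hours with a median of 0.77 and 5 of 21 rising (adjusted p = 7.81e-06, but adjusted p = 0.073 with an estimated correlation). They had a median of 0.45 at 48 hours (adjusted p = 1.31e-05, but adjusted p = 0.0807 with an estimated correlation), and adjusted over the list alone 7 and 3 were higher at these 2 times. Pik3r1 was higher by 3.03, 2.69 and 2.69 (SE 0.25 each) at 24 hours, 48 hours and 1 week. Atp7a, a copper transporter, was higher by 2.82, 2.60 and 2.97 (SE 0.49 each). These values depended on the floor. With a floor at the 40th percentile Atp7a was at 1.52 (adjusted p = 0.0523) and 1.30 (adjusted p = 0.158) at 24 and 48 hours, and with a floor of 100 units it was at 1.06 (adjusted p = 0.152), 0.84 (adjusted p = 0.489) and 1.21 (adjusted p = 0.123). The muscle factor Mef2c was higher by 2.39 ± 0.38 at 1 week (other probe sets 1.94 and 3.5, both passing, and 0.11).

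The sham counts were 602 at 1 hour (352 higher, 250 lower), 342 at 4 hours (208 and 134), 118 at 24 hours (83 and 35), 94 at 48 hours (79 and 15) and 73 at 1 week (62 and 11). With the CreX signal as a covariate, added after the data were seen, they were 86, 51, 32, 145 and 46, and Myl2 at 1 hour was at -1.27 (adjusted p = 0.697). With this covariate the sarcomere list had medians of 0.32, 0.38, 0.25, 0.23 and 0.19, losing its call at 1 hour (adjusted p = 0.0608), 24 hours (adjusted p = 0.0553) and 1 week (adjusted p = 0.116). Without sham mouse 5 of 8 weeks the counts were 255, 122, 31, 48 and 33. Other single arrays that moved one by over 1.5 times were sham mouse 6 of 8 weeks (309 at 1 hour, 188 at 4 hours, 70 at 24 hours), sham mouse 6 of 1 hour (346) and sham mice 1 and 2 of 4 hours (157 and 174). The rest were sham mice 11, 12 and 13 of 24 hours (39, 237 and 57), sham mice 15 and 17 of 48 hours (47 and 51) and sham mice 6 and 7 of 1 week (43 and 38).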

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

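The differences between successive times, the tests of the 3 patterns weighed below and the restriction to control probe sets of a single strand were chosen after the data were seen.

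The banding difference depended on time in the F test for 28 of the genes that were chosen by size or by this test in the banding comparisons or fixed in advance. It also did for Nrp1 (adjusted p = 0.0122), Ifit1 (0.019), Hadh (0.0363), Abcc9 (0.0374) and Vwf (0.0483), named in the report for other tests or as list members. Matrix and secreted proteins were Serpinf1 (adjusted p = 0.000842), Postn (0.00135), Bgn (0.00261), Timp1 (0.00261), Ltbp2 (0.0262), Col5a2 (0.0264), Col1a2 (0.0298), Col3a1 (0.0312), Fn1 (0.0312), Mfap5 (0.0363) and Fbln2 (0.0374). Genes of metabolism were Pcyox1 (0.00699), Ces1d (0.0329), Cmbl (0.0361), Xdh (0.0363), Isoc1 (0.0387) and Pdk4 (0.0419). The others were Dynll2 (0.000102), Rraga (0.00261), Mtm1 (0.00473), Crebbp (0.0103), Tbcel (0.0214), Fkbp4 (0.0221), Dgcr2 (0.0363), Ebf2 (0.0419), Fhl1 (0.0433), Ift81 (0.0483) and Rnf2 (0.0494). These calls depended on the fit. With the conflicting array put at 48 hours, Dynll2, Serpinf1, Postn, Timp1, Bgn and the other Col1a1 probe set (adjusted p = 0.00173) alone passed of these genes. With a prior variance without trend, where 26 were kept, Rraga, Mtm1, Pcyox1, Crebbp, Ifit1, Tbcel and Ltbp2 passed besides them.

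The difference between successive times in the effect of banding was tested for each list at each of 5 steps. Of these 150 tests 27 passed with the preset correlation and 0 with the estimated correlation, where the smallest adjusted p was 0.287. Medians with adjusted p follow. From 4 to 24 hours sarcomere genes moved up (0.53, 0.00487), as did matrix genes (0.24, 0.00897).

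From 24 to 48 hours, mitochondrial genes (-0.52, 1.02e-14), fatty acid oxidation genes (-0.60, 4.36e-12), glucocorticoid-responsive genes (-0.87, 0.000436) and sarcomere genes (-0.56, 0.000595) moved down. So did endothelial markers (-0.29, 0.00487), calcium handling genes (-0.27, 0.0106), glycolysis genes (-0.38, 0.0189) and heat shock genes (-0.43, 0.0195). Matrix genes (0.56, 4.96e-05), cell cycle genes (0.84, 0.000436), macrophage markers (0.63, 0.00359) and class II antigen presentation genes (0.62, 0.0485) moved up.

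From 48 hours to 1 week, glucocorticoid-responsive genes (0.41, 0.000213), fatty acid oxidation genes (0.33, 0.000436), interferon genes (0.38, 0.00532), mitochondrial genes (0.21, 0.00635) and endothelial markers (0.37, 0.00725) moved up and neutrophil markers down (-0.48, 0.00536). From 1 week to 8 weeks mitochondrial genes moved up (0.27, 7.88e-10). Interferon genes (-0.42, 0.000436), matrix genes (-0.31, 0.000536), macrophage markers (-0.32, 0.000596), cell cycle genes (-0.53, 0.0033), glucocorticoid-responsive genes (-0.39, 0.0061) and fetal genes (-0.28, 0.0231) moved down.

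Sarcomere genes were dimmer, and interferon genes brighter, on the 8 week sham arrays than on the earlier ones. A narrower signal range of those arrays may account for part of the first, since 6 sense-strand exogenous control transcripts, which owe nothing to the ventricle, differed in the same direction by a median of 1.09 (0.89 over the 12 of both strands). Over the trend with brightness the sarcomere list kept a median excess of 0.37 (quartiles 0.13 to 0.99), against a median difference of 0.82, so whether range is the whole cause cannot be told. More degraded RNA could add to it, with a Gapdh 3 prime to 5 prime log2 ratio higher by 0.38. For interferon genes an excess of -0.73 (quartiles -1.06 to -0.23) rules out range, leaving biology such as age, or batch, untested. Without sham mouse 6 of 8 weeks the list was lost at 24 hours and 1 week only.

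For 13 of the 17 probe sets called at 1 hour, the sham group lay farther from the other shams than the banded group did. A shift of the sham mice, such as a batch effect, may account for them rather than banding. The exceptions were Btg2, Cdkn1a, Ebf2 and Pla2g5. The labels hold no batch to test these against each other.

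Banded mouse 5 of 24 hours lacked the shifts of the other 2 mice, with list means of 0.05 for extracellular matrix and its processing, 0.07 for inflammatory cytokines and acute phase and -0.04 for macrophage and myeloid markers. Its mean of 0.50 over fetal and hypertrophy genes, against -0.06 to 0.08 in 3 sham mice, argues against a mislabelled sham of 24 hours. Its CreX signal of 33141 (others of that time 16017 to 36637) argues against a compressed range. A milder band, slower response or label of another time could be the cause and was not tested.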

How the results depend on the processing

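The floor of 100 signal units, the CreX signal (a spike-in control) as a covariate and the removal of the 3 arrays of low range were chosen after the data were seen.

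Outside the leave-one-out fits, the 166 named gene results with a call kept it in 1654 comparisons with an alternative and lost it in 264, and lists kept it in 1070 and lost it in 149. With 1 array left out, these genes kept it in 1867 and lost it in 371, and lists kept it in 3309 and lost it in 75. Counts ranged with 1 array left out from 3 to 53 at 1 hour, 0 to 30 at 4 hours, 11 to 280 at 24 hours, 106 to 1002 at 48 hours, 4 to 63 at 1 week, 0 to 12 at 8 weeks and 288 to 517 on average over times. Time dependence ranged from 30 to 367, the sham time course from 388 to 772, the sham comparisons of 1, 4, 24 and 48 hours and 1 week from 255 to 653, 122 to 378, 31 to 237, 47 to 108 and 33 to 84, and list calls from 59 to 71. No alternative moved the average over times by over 1.5 times.

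Quantile normalization left 1 call at 4 hours, and turned the cytosolic ribosomal list at sham 1 week to -0.07 (adjusted p = 0.735). A floor at the 40th percentile gave 28 at 1 hour and 1 at 4 hours, and the floor of 100 gave 29, 1 and 170 at 1, 4 and 24 hours. Testing the probe sets above the median alone gave 11 at 1 hour, 217 at 24 hours and 176 for time dependence. Array weights gave 4, 1, 1077 and 31 at 1 hour, 4 hours, 48 hours and 8 weeks, 237 for time dependence, 1158 for the sham time course, and 577, 417, 319 and 133 for sham 4, 24 and 48 hours and 1 week. The cause was not tested.

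A prior variance without trend gave 0, 61, 384 and 20 at 4, 24 and 48 hours and 1 week, 26 for time dependence, and 63 and 60 for sham 24 and 48 hours. With the array of conflicting labels put at 48 hours there were 0, 375 and 20 calls at 4 hours, 48 hours and 1 week. With only the 6 arrays of a time, which leaves 4 residual degrees of freedom, there were 0, 0, 2, 0, 8 and 1. The estimated correlation left 21 of 63 list calls. The cause was not tested for the others.

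The CreX covariate gave 5 at 4 hours, 252 at 24 hours, 172 for time dependence, 246 for the sham time course, and 86, 51, 32, 145 and 46 for the 5 sham comparisons. It turned the endothelial list at sham 1 hour to 0.00 (adjusted p = 0.966) and Myl2 there to -1.27 (adjusted p = 0.697). Without the arrays of low range there were 0, 178 and 1020 calls at 4, 24 and 48 hours and 295 for time dependence. The cause was not tested.

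No paired analysis was possible for banding because banded and sham mice of a time share fewer than 2 replicate numbers. Sham mice of 1 hour, 1 week and 8 weeks share numbers, and with the replicate block sham 1 hour and 1 week had 311 and 40 calls, against 421 and 46 unpaired on the same arrays.

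Without 1 array in turn, the counts that moved by over 1.5 times stand beside each result. At 4 hours the remaining ones were 7 without banded mouse 5 of 24 hours or banded mouse 10 of 48 hours, 5 without banded mouse 4 of 24 hours, and 1 for the rest. Signals near the floor of 19.2 limit what could be called, and 2611 probe sets listed at 0 could not be tested.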

Other observations

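The permutation tests of the counts, all but that of the list calls, were written down only after the counts were seen.

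Some groups of genes showed no call in any banding comparison. Skeletal muscle genes came closest at 48 hours (adjusted p = 0.0525), followed by oxidative stress genes at 8 weeks (0.0525), lung epithelium markers at 1 hour (0.066), class II antigen presentation at 48 hours (0.0711), lymphocyte markers at 1 hour (0.16), vasoactive genes at 4 hours (0.175) and circadian genes (0.254). Red blood cell and adipocyte markers had a smallest adjusted p of 0.411 each. At 48 hours 3 single circadian genes still fell, Per2 (-1.97), Nr1d2 (-1.48) and Usp2 (-0.95).

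In sham mice against 8 weeks, further lists passed with the preset correlation alone. Endothelial markers had medians of -0.41 and -0.53 at 1 and 4 hours (adjusted p = 0.0275 and 0.00586, but adjusted p = 0.177 and 0.09 with an estimated correlation). Fatty acid oxidation genes had 0.31 and 0.23 at 24 and 48 hours (adjusted p = 0.00436 and 2.11e-05, but adjusted p = 0.632 and 0.414 with an estimated correlation). Lymphocyte markers had 0.51 at 24 hours (adjusted p = 0.0429, but adjusted p = 0.588 with an estimated correlation) and immediate early genes 0.35 at 48 hours (adjusted p = 0.000276, but adjusted p = 0.177 with an estimated correlation). At 1 week calcium handling genes had 0.20, cytosolic ribosomal proteins 0.07 and fibroblast markers 0.24 (adjusted p = 0.0183, 0.0288 and 0.0429, but adjusted p = 0.177, 0.572 and 0.303 with an estimated correlation). With the CreX covariate endothelial markers were at 0.00 and -0.05 (adjusted p = 0.966 and 0.863) and lymphocyte markers at 0.08 (adjusted p = 0.559), and calcium handling (adjusted p = 0.0576) and ribosomal genes (adjusted p = 0.546) did not pass. Quantile normalization ended the endothelial call at 1 hour and those of fatty acid oxidation genes, lymphocyte and fibroblast markers and ribosomal proteins (adjusted p from 0.0635 to 0.735). Among probe sets above the median signal endothelial markers did not pass (adjusted p = 0.205 and 0.0605). Array weights ended the 3 calls of 1 week (adjusted p from 0.0678 to 0.104), and a floor of 100 signal units that of fibroblast markers (adjusted p = 0.0645). Leaving out single arrays ended the calls of these 3 lists and of lymphocyte and fatty acid oxidation genes at 24 hours.

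Group labels were permuted to ask whether the counts could arise by chance. With 3 mice against 3 there are 10 splits, too few to exclude chance. As many calls as the real grouping came in 1 of 10 splits at 1 hour (17, highest other 5), 1 at 4 hours (3, highest other 2), 1 at 24 hours (107, highest other 8), 1 at 48 hours (586, highest other 0), 1 at 1 week (53, highest other 0) and 2 at 8 weeks (3, highest other 4). For sham against 8 weeks it was 1 of 10 at 1 hour (602, highest other 1), 4 hours (342, highest other 2), 24 hours (118, highest other 0), 48 hours (94, highest other 0) and 1 week (73, highest other 0).

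Of 100 groupings over all times (real one included), 2 reached the count for the average over times (368 calls, highest other 395). For time dependence 3 did (114, highest other 241). Only the real one reached the list calls (63, median of others 22, highest other 49) and the sham time course (579, highest other 183). Unadjusted over tests, these shares leave chance open for the first 2. The draws beyond the real counts (395, 161 and 241) had kept the real split of 48 hours or its mirror image.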
